A study of Homo sapiens with 9 samples.

How the data were processed

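Gene expression was measured on 9 Illumina bead arrays from LNCaP cells, an established human prostate cancer cell line grown in RPMI medium with 10% serum. Per the labels' protocols, the cells were infected in triplicate with 1 of 3 lentiviral pLKO.1 constructs, and RNA was taken 3 days after infection. The scrambled control hairpin (shScr) has the target sequence CCTAAGGTTAAGTCGCCCTCG. The hairpin ETV1sh1 is aimed at GTGGGAGTAATCTAAACATTT in an untranslated region of ETV1, read here as the 3′ UTR, and the hairpin ETV1sh2 at CGACCCAGTGTATGAACACAA in exon 7. Per the labels' protocols, about 500 ng of total RNA per sample was amplified and labelled with biotin. Each of the 3 groups has 3 arrays, assigned by the sample titles. The labels do not say whether the 3 infections of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Slide positions were not given in the sources used here.

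The deposited table of 48803 probes holds an intensity per probe and array, a linear signal that was not normalized per the file headers and not background-subtracted, as no value was 0 or below. Beside each intensity the authors deposited a detection p-value, which sets the probe against the negative-control beads of the same array. A further deposited table holds the authors' normalized values, which the values show to be on a log2 scale, with the same quartiles on all 9 arrays and the same order of probes as the intensity of the same array. BeadStudio and Partek are named in the submitters' processing notes, with versions and settings not given in the sources used here. Of the probes, 28098 were paired with 1 gene by the platform annotation used here, 13 with several genes and 20692 with no gene. Gene names were matched by Entrez number for 28059 probes and by accession for 14, and 25 names were kept as annotated, while 7 symbols were updated. Probes with several genes or no gene were named nowhere and were tested separately as probes.

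The intensities were corrected for background and normalized with neqc of limma 3.58.1 in R 4.3.3, which uses the detection p-values to estimate the background, adds an offset of 16, takes quantiles across arrays and gives log2 values. A probe was kept where its detection p was under 0.05 on at least 3 of the 9 arrays. Of the probes of 1 gene, the probe with the highest mean over all 9 arrays stood for the gene, which left 11023 genes. Among 2559 genes with several kept probes, probes were called in both directions for 10 genes with ETV1sh1, for 9 with ETV1sh2 and for 4 between the hairpins. All 9 arrays entered 1 linear model with a mean per group (lmFit and eBayes of limma), and every adjusted p for a gene is from this model with the Benjamini-Hochberg adjustment, two-sided, with a threshold of 0.05 and no fold minimum. The contrasts were ETV1sh1 against shScr, ETV1sh2 against shScr, the mean of both hairpins against shScr, and ETV1sh1 against ETV1sh2. Errors given with ± are standard errors of the fitted log2 fold change from 3 arrays per group unless named SD. They rest on 1 spread per gene, pooled over all 9 arrays and moderated across genes. A gene therefore has the same error with both hairpins, and the error does not show the spread of the groups named. Where a gene was detected on no array of a group, the fold is given as at least the ratio of the brighter group's mean to a floor. The floor is the mean, over the dim group's arrays, of the lowest detected signal or the gene's own signal, whichever was higher, on the normalized log2 scale.

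A total of 26 gene lists with 620 genes, of which 571 have a named probe, were written from general knowledge before the data were examined. So were the test, the samples in each fit, the other settings to be tried and the rule for naming genes. The lists were tested with camera of limma with a preset correlation of 0.01, adjusted over the 26 lists of a contrast, and beside it with an estimated correlation and with fry, which tests whether a list's genes move on balance in 1 direction without comparing them with other genes. A call lost with an estimated correlation does not by itself show correlated members, since calls were lost also where the estimate was below 0.01. The naming rule took 9 genes always, among them ETV1, FOXA1, HOXB13, KLK3, KLK2, FKBP5 and TMPRSS2. It further took the 12 highest and 12 lowest genes called the same way by both hairpins, by their mean log2 fold change. It also took the 6 highest and 6 lowest called genes of each hairpin and of the comparison between hairpins, and up to 4 members of each list with the smallest p. Any gene outside this rule is said to be so where it is named. The other 2 of the 9 genes and 1 of the 26 lists are not reported here, although that list was tested and counts in the adjustment.

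Comparisons against the same control arrays share the chance values of those arrays. Unchanged groups were therefore simulated 100 times against the 3 control arrays, and the overlap of independent lists was computed per direction. The steps were tested on simulated data with 200 changed genes among the 11023. At simulated log2 changes of 0.58, 1 and 2, the ETV1sh1 fit recovered 43.7%, 87.6% and 98.5% of the changed genes, the ETV1sh2 fit 42.4%, 89.0% and 98.3%, and the mean of both hairpins 60.6%, 93.0% and 99.2%. False calls made up 6.04%, 5.12% and 5.04% of the calls in these 3 fits. The simulated arrays of a gene had the same spread in every group. In the data the median SD of a gene was 0.18 with shScr, 0.14 with ETV1sh1 and 0.11 with ETV1sh2. The simulated percentages therefore do not give the rates of recovery or of false calls under such unequal spreads. A list shifted by -0.3 was found in 50 of 50 simulations, with 4 false calls over the 25 other lists in all 50 simulations. Genes were drawn independently in these simulations too, so they do not give the rate of false calls for lists whose genes move together. Only 3 arrays per group limit the precision.

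The other settings tried were no background correction, an offset of 50, scaling to a common median, the authors' normalized values, no filter on dim probes, detection p under 0.01 on all 9 arrays, the mean of a gene's probes, only the 2 groups compared in the fit, array weights, a trended robust prior, the replicate number as a block, leaving out each array in turn, a 1.5-fold minimum, an adjusted p threshold of 0.01, all probes counted as probes, both other list tests and split controls. Alternatives added after seeing the data left out the 2 arrays least like their own group (shScr 1 and ETV1sh1 2), left out the 2 arrays of highest background (shScr 3 and ETV1sh1 2), or added the background level as a covariate. Matches of the hairpins' seed sequences to transcripts were planned and not run, since no transcript sequences were used here. A block for the slide was planned and not run, since no slide was given. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.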

Results

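The series asks which genes change in LNCaP prostate cancer cells when ETV1, an ETS-family transcription factor, is targeted by RNA interference. Genome-wide RNA levels were measured 3 days after infection in 3 arrays each with the scrambled hairpin shScr, the hairpin ETV1sh1 and the hairpin ETV1sh2. Mean signals per array ran from 313 to 400, and 30.1% to 34.6% of probes were detected per array. The median background signal lay between 34.9 and 49.2, highest on ETV1sh1 2 (49.2) and shScr 3 (48.5). Across genes, which are not independent replicates, arrays of 1 group correlated at 0.980 to 0.994 and arrays of different groups at 0.955 to 0.980. The first 3 principal components held 39.5%, 28.0% and 12.2% of the variance.

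The targeted gene was not measurable. ETV1 had 1 named probe, which was detected on 0 of the 9 arrays, with detection p between 0.331 and 0.875. Its mean signal was 44.1 ± 4.4 (SD, n = 3) with shScr, 34.5 ± 8.8 with ETV1sh1 and 35.4 ± 1.7 with ETV1sh2, all below the level needed for detection, so no fold is given. The arrays therefore do not show whether ETV1 RNA was lower with either hairpin, and the group labels could not be checked through it.

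With ETV1sh1, the matrix metalloproteinase MMP7 fell by 4.12 ± 0.12 on the log2 scale against shScr (adjusted p = 1.85e-07), the deepest fall of any gene called. The serine protease KLK3, known as prostate-specific antigen and induced by androgen, fell by 1.27 ± 0.23 (adjusted p = 0.0047). The androgen-induced protease TMPRSS2 fell by 0.67 ± 0.11 (adjusted p = 0.00262) and the co-chaperone FKBP5 by 0.92 ± 0.13 (adjusted p = 0.0015). The highest rise was that of STMN4, a stathmin-family regulator of microtubules, which was detected on 0 shScr arrays and was at least 54.8-fold higher with ETV1sh1 (adjusted p = 4.05e-08). The lists of DNA replication, mitosis and androgen-induced genes fell, while androgen-repressed genes rose, a call lost with an estimated correlation (adjusted p = 0.0854).

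A total of 2572 of 11023 genes changed with ETV1sh1, 1518 higher and 1054 lower (59.0% higher), of which 157 and 154 by at least 2-fold. The vesicle protein SYT11, not detected with shScr, rose at least 9.28-fold. The keratin KRT80 rose by 3.18 ± 0.17 (its other probe by 1.33), the small heat shock protein HSPB8 by 2.65 ± 0.12, the oxidase RNLS (renalase) by 2.50 ± 0.13 and the intermediate filament vimentin (VIM) by 2.27 ± 0.24. Among the deepest falls after MMP7, RIPOR2 fell by 3.25 ± 0.17, the lipid phosphatase PLPP1 by 2.28 ± 0.15, the protease inhibitor PI3 (elafin) by 2.23 ± 0.18 and RRM2, a ribonucleotide reductase subunit that supplies DNA precursors, by 2.21 ± 0.37. PI3 and RRM2 were each detected on 1 of 3 ETV1sh1 arrays, near background, so the sizes of these falls are not exact. The beta-defensin DEFB132 was detected on 0 ETV1sh1 arrays and was at least 4.17-fold lower. The pioneer factor FOXA1 (0.18 ± 0.10, adjusted p = 0.242), the prostate homeobox factor HOXB13 (-0.21 ± 0.12, adjusted p = 0.235) and the kallikrein KLK2 (-0.53 ± 0.19, adjusted p = 0.0696) did not pass. The 3 ETV1sh1 arrays lay beyond all 3 shScr arrays for the 41 named genes called, which were chosen by size and p, so that the 10% given by chance for 1 gene taken without regard to its values does not apply. The total fell to 1687 in a fit of only the groups compared, where the ETV1sh2 arrays no longer enter the error. Their median gene SD was the lowest, at 0.11 against 0.14 with ETV1sh1 and 0.18 with shScr. The genes called higher fell to 1007 without ETV1sh1 3. KLK2 passed in 8 of 23 alternatives, among them those without shScr 1 (adjusted p = 0.00816), with array weights (0.00631), with no background correction (0.0467) and among genes detected on all 9 arrays (0.0287), over a range of 0.00631 to 0.202.

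**Figure D1:**
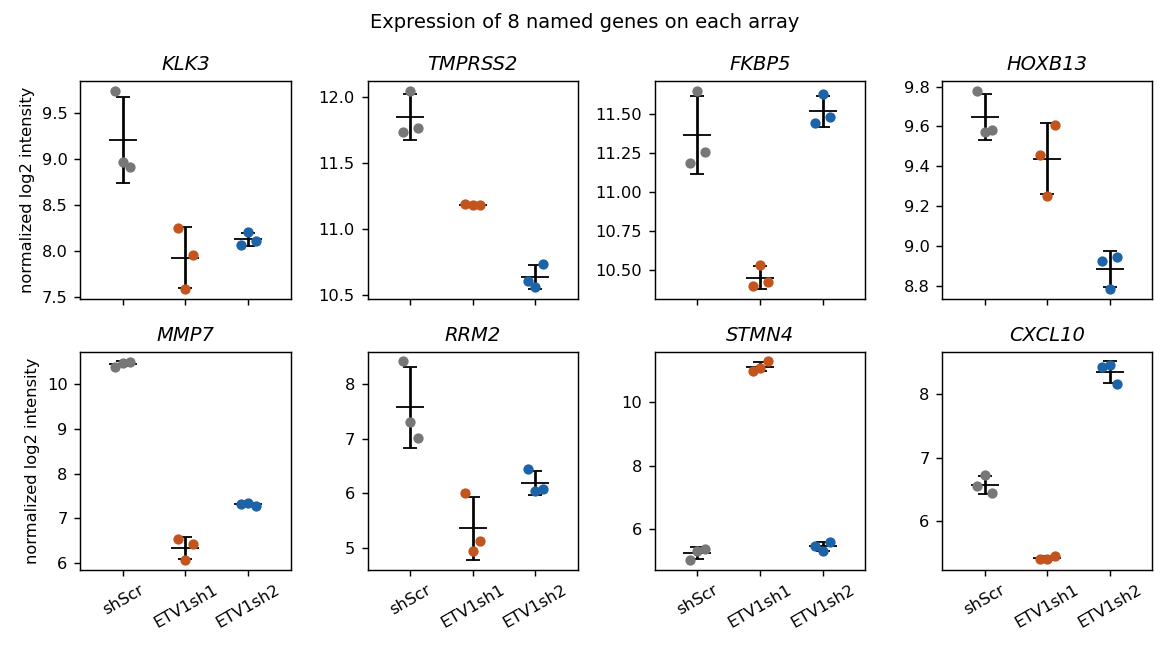
Normalized log2 intensity of KLK3, TMPRSS2, FKBP5, HOXB13, MMP7, RRM2, STMN4 and CXCL10, with 1 point per array for shScr, ETV1sh1 and ETV1sh2, and the mean and SD of 3 arrays as horizontal and vertical lines. KLK3, TMPRSS2 and MMP7 lie lower with both hairpins, FKBP5 is lower with ETV1sh1 than with ETV1sh2 (difference -1.07), and STMN4 is higher with ETV1sh1 than in both other groups.

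Of 26 gene lists, 9 moved past the camera threshold with ETV1sh1. Among androgen-induced genes, 0 rose and 14 of 23 fell, and 16 fell when adjusted over the list alone (camera adjusted p = 2.81e-08). PLPP1, MPHOSPH9 (adjusted p = 0.000444), CENPN (-0.71 ± 0.08) and FKBP5 had the smallest p. Of the DNA replication and S phase genes, 16 of 33 fell and 0 rose, 18 adjusted over the list alone (camera adjusted p = 2.81e-08). Examples were UHRF1 (-1.15 ± 0.12), which maintains DNA methylation at replication, GINS4 (-0.75 ± 0.09), PRIM1 (-0.76 ± 0.10) and the helicase subunit MCM4 (-0.72 ± 0.10). Of the mitosis genes, 11 of 34 fell and 0 rose, 14 adjusted over the list alone (camera adjusted p = 3.51e-06). Those that fell included TOP2A (-0.94 ± 0.09), CCNB2 (-0.99 ± 0.10), CDC25C (-0.70 ± 0.09) and KIF23 (-0.94 ± 0.16). The calls of these 3 lists held with an estimated correlation, at adjusted p = 0.0361, 0.0361 and 0.0364. Without ETV1sh1 1, without ETV1sh1 3, or without both arrays of highest background, 10 of the DNA replication and S phase genes fell.

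The other 6 lists called with ETV1sh1 lost the call with an estimated correlation. That correlation was below the preset 0.01 for androgen-repressed genes (-0.0019), fibroblast (-0.056) and leukocyte markers (-0.092). For these lists the loss does not show that members move together. Of the NF-kB and inflammatory response genes, 6 of 12 fell and 0 rose, 6 adjusted over the list alone (camera adjusted p = 0.00143; adjusted p = 0.188 with an estimated correlation). They included the chemokines CXCL8 (-1.92 ± 0.13), CCL20 (-1.51 ± 0.13) and CCL2 (-1.11 ± 0.20, detected on 2 of 3 ETV1sh1 arrays) and the NF-kB inhibitor NFKBIA (-0.56 ± 0.09). Androgen-repressed genes rose in 6 of 9 cases and fell in 0, 7 adjusted over the list alone (camera adjusted p = 0.00423; adjusted p = 0.0854 with an estimated correlation). Higher members included the androgen-inactivating glucuronosyltransferases UGT2B15 (1.88 ± 0.27) and UGT2B17 (1.55 ± 0.14), CAMK2N1 (0.80 ± 0.13) and GRB10 (0.52 ± 0.10). With the mean of its probes GRB10 was at 0.29 and lost the call (adjusted p = 0.0622, range over the alternatives 0.000745 to 0.0622). In hypoxia and glycolysis, 5 of 25 genes fell and 2 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.00621; adjusted p = 0.188 with an estimated correlation). The glucose transporter SLC2A1 (-0.79 ± 0.12), PFKFB3 (-0.90 ± 0.13) and ANKRD37 (-0.65 ± 0.11) fell, while the glucose transporter SLC2A3 rose by 0.86 ± 0.09.

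Some markers of other cell types moved with ETV1sh1 too, though most markers listed were not among the genes tested. Tested were 9 of 22 fibroblast and stromal, 7 of 19 neuroendocrine and 6 of 19 leukocyte markers. Of the fibroblast and stromal markers, 4 of 9 rose and 0 fell, 4 adjusted over the list alone (camera adjusted p = 0.00783; adjusted p = 0.0972 with an estimated correlation). These were VIM, the smooth muscle actin ACTA2 (1.84 ± 0.12), the collagen COL1A1 (1.70 ± 0.15) and TAGLN (0.70 ± 0.18). The neuroendocrine markers TUBB3 (1.67 ± 0.10), ENO2 (0.89 ± 0.13) and SYP (detected on 0 shScr arrays, at least 1.44-fold) rose, 3 of 7 with 0 lower, 3 adjusted over the list alone (camera adjusted p = 0.0279; adjusted p = 0.156 with an estimated correlation). Of the leukocyte markers, LCP1 (-0.76 ± 0.09) and HLA-DRA (-0.53 ± 0.12) fell, 2 of 6 with 0 higher, 3 adjusted over the list alone (camera adjusted p = 0.0344; adjusted p = 0.156 with an estimated correlation). The neuroendocrine call was lost without shScr 1 (adjusted p = 0.0611) or ETV1sh1 1 (0.0687), and the leukocyte call without shScr 1 (0.0807), shScr 3 (0.0513) or ETV1sh1 1 (0.0687). Without a filter on dim probes the fibroblast (0.0705), neuroendocrine (0.163) and leukocyte (0.442) calls all ended. Among the genes, SYP missed the threshold without shScr 1 (0.0572) or shScr 3 (0.0503), TAGLN without ETV1sh1 1 (0.0725) or ETV1sh1 2 (0.0638), and HLA-DRA without ETV1sh1 1 (0.0521).

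With ETV1sh2, MMP7 fell by 3.15 ± 0.12 on the log2 scale (adjusted p = 6.61e-06), again the deepest fall, and TMPRSS2 fell by 1.22 ± 0.11 (adjusted p = 7.56e-05). KLK3 fell by 1.08 ± 0.23 (adjusted p = 0.00666) and HOXB13 by 0.76 ± 0.12 (adjusted p = 0.00119). FKBP5 did not change detectably (0.15 ± 0.13, adjusted p = 0.407). Genes of DNA replication fell. The interferon response and steroid metabolism lists rose by camera, calls lost with an estimated correlation (adjusted p = 0.0784 for each), and the highest steroid genes by fitted change were AKR1C3 (detected on 0 shScr arrays, at least 3.97-fold higher) and AKR1C2 (2.11 ± 0.19), enzymes that reduce steroid hormones.

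In all, 3734 of 11023 genes changed with ETV1sh2, 2282 higher and 1452 lower (61.1% higher), 348 and 229 of them by at least 2-fold. The highest rises were those of RNLS (2.79 ± 0.13), IFI27L2 (2.59 ± 0.20), an interferon-inducible gene detected on 1 of 3 shScr arrays, the secreted synaptic protein CBLN2 (2.57 ± 0.13), the LIM-domain protein FHL2 (2.40 ± 0.18), also detected on 1 shScr array, the autophagy receptor OPTN (2.22 ± 0.18) and the testis bromodomain protein BRDT (2.22 ± 0.14). After MMP7, the deepest fitted falls were those of the bicarbonate transporter SLC4A4 (-2.58 ± 0.22), RIPOR2 (-2.44 ± 0.17), HDDC2 (-2.38 ± 0.10), the leucine-breakdown enzyme subunit MCCC2 (-2.33 ± 0.39) and the thymidylate synthase TYMS (-2.14 ± 0.16). BRDT was detected on 2 of 3 shScr arrays and SLC4A4 on 2 of 3 ETV1sh2 arrays, near background, as IFI27L2 and FHL2 were with shScr. The sizes and ranks of these genes are therefore not exact. FOXA1 (-0.09 ± 0.10, adjusted p = 0.540) and KLK2 (-0.40 ± 0.19, adjusted p = 0.132) did not pass. KLK2 passed in 3 of 23 alternatives, without shScr 1 (adjusted p = 0.0117), without the 2 arrays least like their group (0.00928) and with array weights (0.00725), over a range of 0.00725 to 0.572. RRM2 (-1.39 ± 0.37, adjusted p = 0.0184) missed the threshold without ETV1sh2 2 (0.0610) or ETV1sh2 3 (0.0576).

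Gene lists past the camera threshold numbered 6 with ETV1sh2. Of the DNA replication and S phase genes, 26 of 33 fell and 0 rose, 28 adjusted over the list alone (camera adjusted p = 2.64e-13; adjusted p = 0.0194 with an estimated correlation). TYMS, MCM4 (-1.38 ± 0.10), UHRF1 (-1.38 ± 0.12) and the replication licensing factor CDT1 (-0.90 ± 0.08) had the smallest p. Of the mitosis genes, 16 of 34 fell and 0 rose, 17 adjusted over the list alone (camera adjusted p = 7.06e-07; adjusted p = 0.0387 with an estimated correlation). Lower members included ANLN (-1.17 ± 0.15), TTK (-0.92 ± 0.13), CDC20 (-0.79 ± 0.09) and TOP2A (-0.66 ± 0.09). Interferon response genes rose in 15 of 26 cases and fell in 0, 17 adjusted over the list alone (camera adjusted p = 1.03e-05; adjusted p = 0.0784 with an estimated correlation). They included the chemokine CXCL10 (1.77 ± 0.11), SAMD9 (1.65 ± 0.15), IFI44 (1.59 ± 0.11) and the transcription factor IRF9 (1.14 ± 0.13). With ETV1sh1, 7 of the 26 rose and 2 fell, 8 and 2 adjusted over the list alone (camera adjusted p = 0.139). The list passed without a filter on dim probes (0.0471), among genes detected on all 9 arrays (0.0304) and with fry (0.0130). The range over the alternatives, both other list tests included, was 0.0130 to 0.420. Among androgen-induced genes, 12 of 23 fell and 4 rose, 14 and 5 adjusted over the list alone (camera adjusted p = 0.000464; adjusted p = 0.0784 with an estimated correlation). CENPN (-1.46 ± 0.08), TMPRSS2 and MPHOSPH9 (-1.07 ± 0.11) fell, while the transcription factor MAF rose by 1.21 ± 0.14. Without ETV1sh2 2, 2 androgen-induced genes rose.

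In androgen and steroid metabolism, 10 of 19 genes rose with ETV1sh2 and 0 fell, 11 adjusted over the list alone (camera adjusted p = 0.00887; adjusted p = 0.0784 with an estimated correlation). Beside AKR1C2 and AKR1C3, the cholesterol side-chain cleavage enzyme CYP11A1 rose by 1.73 ± 0.16 and HSD17B10 by 0.95 ± 0.11. Of the fibroblast and stromal markers, 6 of 9 rose and 0 fell, 6 adjusted over the list alone (camera adjusted p = 0.00887; adjusted p = 0.0784 with an estimated correlation). ACTA2 rose by 1.89 ± 0.12, with COL1A1 at 1.21 ± 0.15, TAGLN at 1.23 ± 0.18 and S100A4 at 0.82 ± 0.18. With the mean of its probes, TAGLN rose by 0.52 and lost the call with ETV1sh2 (adjusted p = 0.157, range over the alternatives 3.47e-05 to 0.157), as it did with ETV1sh1 (0.145, range 0.00592 to 0.145) and in the mean of both hairpins (0.0943, range 0.000108 to 0.0943). The steroid list call was lost among genes detected on all 9 arrays (adjusted p = 0.231), and the fibroblast call there (0.0735) and without a filter on dim probes (0.0646).

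**Figure D2:**
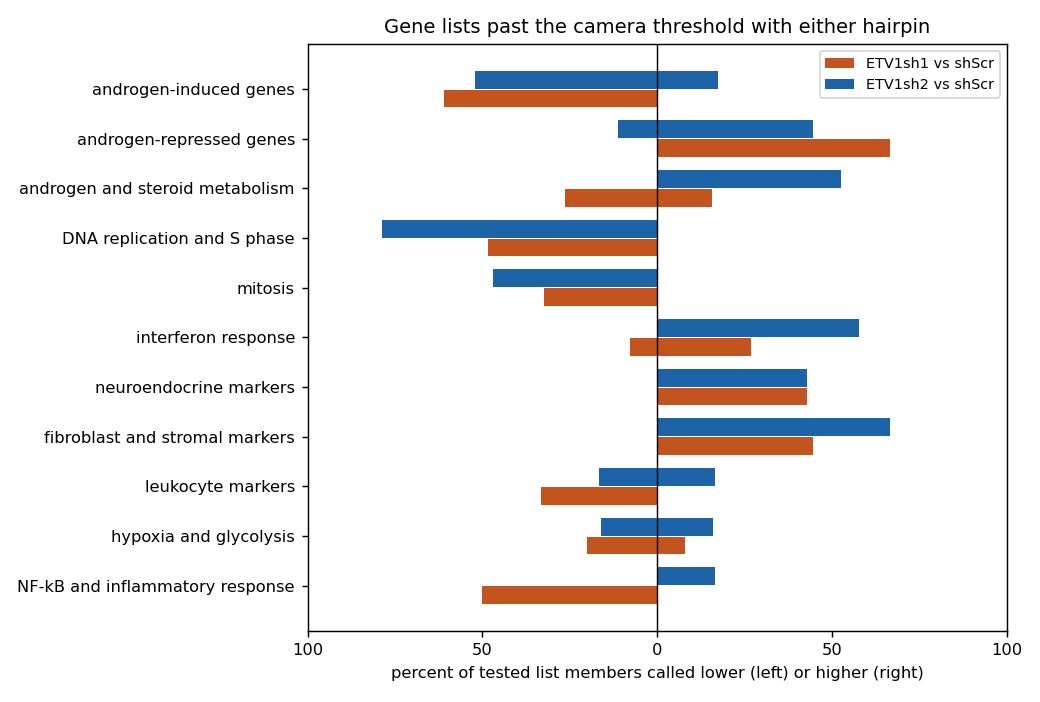
Percent of the tested members of each gene list that were called lower (left of 0) or higher (right of 0) with ETV1sh1 and ETV1sh2 against shScr, for the lists past the camera threshold with either hairpin. DNA replication and S phase, mitosis and androgen-induced genes lie mainly to the left with both hairpins, and the interferon response lies to the right with ETV1sh2 (15 of 26 genes).

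MMP7, RIPOR2, KLK3 and TMPRSS2 fell and RNLS, ACTA2 and TUBB3 rose with both hairpins. A total of 1445 genes were called the same way by both hairpins, 938 higher and 507 lower, where independent lists of these sizes would share 314 and 139. A further 114 genes were called in opposite directions, where independent lists would share 200 and 218. Both comparisons use the same shScr arrays, which draws calls the same way, so the lists are not independent. With whole groups exchanged, so that a hairpin group stood as the shared control, 1512 genes were called the same way. The 1445 are therefore not particular to shScr as the control. Among the 12 highest of the shared genes were ACTA2 (1.84 and 1.89 with ETV1sh1 and ETV1sh2), the microtubule end-binding protein MAPRE3 (1.83 and 1.78), the hormone carrier TTR (1.84 and 1.72), the dynein light chain DYNLRB1 (1.58 and 1.77) and the neuronal tubulin TUBB3 (1.67 and 1.65). Among the 12 lowest were the exocytosis factor CADPS2 (-1.93 and -2.06), the aminotransferase AADAT (-1.45 and -1.91), FAM72B (-1.69 and -1.44), RPRML (-1.15 and -1.97), the engulfment adaptor GULP1 (-0.96 and -2.11), the laminin LAMA1 (-1.45 and -1.61) and the importin KPNA2 (-1.23 and -1.75). KRT80 was among the highest by its mean, but its other probe did not rise with ETV1sh2 (-0.05), and the mean of its probes ended the call there (adjusted p = 0.104). The other probe of KPNA2 was at -0.09 with ETV1sh1 and -0.75 with ETV1sh2, so that the size of its fall differs between probes. GULP1 missed the threshold with ETV1sh1 without any single ETV1sh1 array (adjusted p = 0.0685, 0.0511 and 0.0847 without 1, 2 and 3), and without shScr 1 it was at -0.59 with ETV1sh1. CADPS2 was detected on 2 of 3 arrays of each hairpin, near background, so its sizes are not exact.

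Across genes, the log2 fold changes of both hairpins correlated at 0.545, with a covariance of 0.115. Arrays simulated without change, with shared simulated controls, gave a correlation of 0.50 (highest 0.526) and a covariance of 0.0150. In these simulations 66.6% of genes had the same sign, against 71.1% observed. Genes were drawn independently there, so the simulated correlations vary less than real ones would. The observed correlation had an SD of 0.031 over fits that left out 1 array. The correlation by itself is not shown to exceed 0.50, a value that shared controls give to unchanged groups of equal size and spread. The covariance lay above the highest simulated value of 0.0162. This argues against the spread of the shared control arrays as the whole source of the shared movement. With the controls split, so that each hairpin had its own control arrays, the correlation was 0.320 to 0.438 over 6 splits. These splits share no control array and leave 1 or 2 of them per hairpin. A difference of shScr as a group would still enter both sides of each split.

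**Figure D3:**
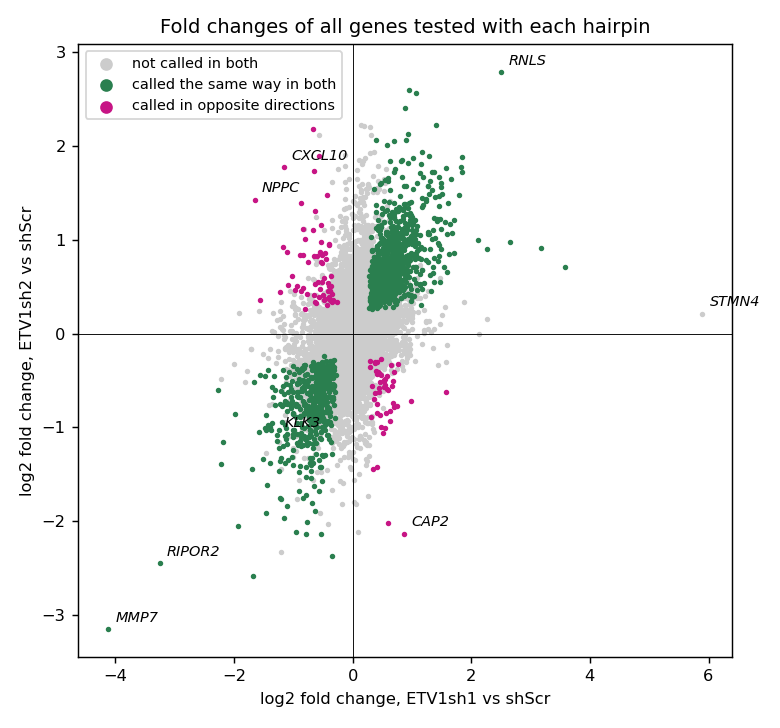
Log2 fold change of each of the 11023 genes with ETV1sh1 (horizontal axis) and with ETV1sh2 (vertical axis) against shScr, coloured by whether both hairpins called the gene the same way (1445 genes), in opposite directions (114) or not both. MMP7 and RNLS lie at the ends of the shared direction, and STMN4 lies along the ETV1sh1 axis alone.

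In the mean of both hairpins, 3489 genes changed, 2114 higher and 1375 lower (60.6% higher), 167 and 110 by at least 2-fold, and 7 lists passed. DNA replication and S phase genes fell in 25 of 33 cases and rose in 0, 30 adjusted over the list alone (camera adjusted p = 5.35e-13; adjusted p = 0.0206 with an estimated correlation). Among these were TYMS (-1.46 ± 0.14), UHRF1 (-1.26 ± 0.11), MCM4 (-1.05 ± 0.08) and PRIM1 (-0.93 ± 0.09). Mitosis genes fell in 19 of 34 cases and rose in 0, 20 adjusted over the list alone (camera adjusted p = 8.12e-08; adjusted p = 0.0278 with an estimated correlation). Of the androgen-induced genes, 14 of 23 fell and 1 rose, 15 and 1 adjusted over the list alone (camera adjusted p = 1.06e-06; adjusted p = 0.0355 with an estimated correlation), with PLPP1 at -1.44 ± 0.13 and CENPN at -1.08 ± 0.07. Interferon response genes rose in 14 of 26 cases and fell in 0, 14 adjusted over the list alone (camera adjusted p = 0.000193; adjusted p = 0.127 with an estimated correlation). Fibroblast and stromal markers rose in 5 of 9 cases and fell in 0, 6 adjusted over the list alone (camera adjusted p = 0.00441; adjusted p = 0.0866 with an estimated correlation). Hypoxia and glycolysis had 5 of 25 genes lower and 2 higher, the same adjusted over the list alone (camera adjusted p = 0.04; adjusted p = 0.323 with an estimated correlation). Androgen-repressed genes had 6 of 9 higher and 0 lower, 6 adjusted over the list alone (camera adjusted p = 0.0491; adjusted p = 0.182 with an estimated correlation). The androgen-repressed call was lost without any single array except shScr 2 and ETV1sh2 2 (adjusted p = 0.0512 to 0.0780). The hypoxia call was lost without shScr 1 (0.0726), shScr 3 (0.107), ETV1sh1 1 (0.0512), ETV1sh1 2 (0.0568) or ETV1sh2 3 (0.0562). Neither of these lists passed camera with ETV1sh2 against shScr. There, androgen-repressed genes had 4 higher and 1 lower (camera adjusted p = 0.395, fry adjusted p = 0.00523). Hypoxia and glycolysis had 4 higher and 4 lower (camera adjusted p = 0.296, fry adjusted p = 0.667).

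The other 13 lists passed in no contrast, and the counts given here, for 12 of them, are for the mean of both hairpins. In the 3 lists of ETS factors, their reported targets and MAPK output, members moved both ways. Of the ETS family members 2 of 17 rose and 3 fell (camera adjusted p = 0.321), with ELF3 at 0.79 ± 0.09, ELK4 at -0.97 ± 0.10, EHF at -1.42 ± 0.19 and SPDEF at -0.42 ± 0.07. Of the reported targets of PEA3-family ETS factors, the subfamily of ETV1, 5 of 12 rose and 2 fell (camera adjusted p = 0.703), with a median of 0.30, a mean of -0.05 and a camera direction of up. MMP7 fell in this list while VIM, CDH3 (0.59 ± 0.10) and MMP10 rose. MMP10 was detected on 0 shScr arrays and was at least 1.72-fold higher with ETV1sh1. Of the MAPK output genes 2 of 14 rose and 5 fell (camera adjusted p = 0.16), among them SPRY1 (-0.96 ± 0.09), SPRY4 (detected on 0 arrays of either hairpin, at least 1.32-fold lower with ETV1sh1 and 1.42-fold with ETV1sh2), SPRED1 (-0.91 ± 0.14) and MYC (-1.02 ± 0.10), and this list passed without a filter on dim probes (adjusted p = 0.0362).

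Lineage and metabolic lists did not pass either. Of the luminal prostate markers 4 of 15 rose and 6 fell (camera adjusted p = 0.461), with CD24 at 1.55 ± 0.08, ACP3 at -0.96 ± 0.09 and STEAP1 at -0.98 ± 0.14. Among basal prostate markers 0 of 6 passed in the limma fit in either direction, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.797). Of the epithelial junction genes 3 of 18 rose and 4 fell (camera adjusted p = 0.45, median 0.02, mean -0.06, direction down). Of the epithelial-mesenchymal transition and TGF-beta genes 2 of 13 rose and 3 fell (camera adjusted p = 0.995, median 0.14, mean 0.08, direction down). Cholesterol synthesis had 1 of 19 genes higher and 1 lower (camera adjusted p = 0.797), with INSIG1 at -0.78 ± 0.09 and SC5D at 0.74 ± 0.10. Fatty acid synthesis had 1 of 15 higher and 2 lower (camera adjusted p = 0.61). Oxidative phosphorylation had 6 of 27 genes higher and 3 lower (camera adjusted p = 0.61). Cytosolic ribosomal proteins had 0 of 35 higher and 1, RPS7 (-1.22 ± 0.21), lower (camera adjusted p = 0.461, median 0.01, mean -0.03, direction down), and histone genes had 1 of 14 higher and 3 lower (camera adjusted p = 0.431). Adjusted over the list alone, the higher and lower counts were 2 and 3 for the ETS family, 5 and 2 for PEA3 targets, 2 and 5 for MAPK output, 6 and 6 for luminal, 0 and 0 for basal, 3 and 5 for junction and 2 and 3 for epithelial-mesenchymal genes. They were 1 and 1 for cholesterol synthesis, 3 and 2 for fatty acid synthesis, 7 and 4 for oxidative phosphorylation, 0 and 1 for ribosomal proteins and 1 and 5 for histone genes.

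Tested directly, ETV1sh1 and ETV1sh2 differed in STMN4 (higher with ETV1sh1 by 5.68 ± 0.13, a fitted value that is no exact fold, since ETV1sh2 arrays lay near background and STMN4 was detected on 2 of these 3) and in the chemokines CXCL10 and CCL8, which were lower with ETV1sh1 and higher with ETV1sh2. CXCL10 fell by 1.15 ± 0.11 with ETV1sh1 and rose by 1.77 ± 0.11 with ETV1sh2 (difference -2.93 ± 0.11, adjusted p = 1.81e-06; detected on 1 of 3 ETV1sh1 arrays), and CCL8 fell by 0.66 ± 0.17 and rose by 2.18 ± 0.17. The natriuretic peptide NPPC moved likewise (-1.65 ± 0.13 and 1.43 ± 0.13), and the actin-binding protein CAP2 the other way (0.86 ± 0.12 and -2.13 ± 0.12). NPPC was detected on 2 of 3 ETV1sh1 arrays, near background, so its sizes are not exact. FKBP5 was lower with ETV1sh1 than with ETV1sh2 (-1.07 ± 0.13, adjusted p = 0.000532), while TMPRSS2 (0.55 ± 0.11, adjusted p = 0.00563) and HOXB13 (0.55 ± 0.12, adjusted p = 0.00833) were lower with ETV1sh2. For KLK3 the difference did not pass (-0.20 ± 0.23, adjusted p = 0.604).

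In total 2557 genes differed between the hairpins, 1150 higher and 1407 lower with ETV1sh1, 172 and 257 of them by at least 2-fold. Other genes higher with ETV1sh1 were SYT11 (2.87 ± 0.10), PPP1R14C (2.62 ± 0.16), a phosphatase inhibitor, KRT80 (2.27 ± 0.17) and the nucleotide-precursor enzyme PRPS1 (2.20 ± 0.12). The other probe of KRT80 differed by 1.38. AKR1C2 (-2.69 ± 0.19) and CYP11A1 (-2.39 ± 0.16) were lower, and the carboxylesterase CES1, detected on 0 ETV1sh1 arrays, was at least 3.49-fold lower. PPP1R14C on ETV1sh2 arrays and CYP11A1 on ETV1sh1 arrays were detected on 2 of 3, near background, so their sizes are not exact. The direct difference was called for the 114 genes moved in opposite directions, which follows from their opposite calls, for 314 of the 1445 moved the same way and for 1746 of the 3188 called with 1 hairpin alone. The 114 became 63 without shScr 2, 74 without shScr 3, 71 without ETV1sh1 1, 53 without both arrays of highest background, 64 in fits of only the groups compared, 180 with array weights, 27 with a 1.5-fold minimum and 29 at an adjusted p threshold of 0.01.

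Of 6 lists that differed between the hairpins by camera, 0 held the call with an estimated correlation, where 5 had an unadjusted p under 0.05, and 6 passed by fry. Interferon response genes were lower with ETV1sh1 than with ETV1sh2 in 9 of 26 cases and higher in 1, 14 and 1 adjusted over the list alone (camera adjusted p = 0.00112; adjusted p = 0.187 with an estimated correlation). Lower ones included CXCL10, SAMD9 (-1.58 ± 0.15), IFIT1 (-1.43 ± 0.12) and IFI44 (-1.33 ± 0.11). DNA replication and S phase genes were higher with ETV1sh1 in 11 of 33 cases and lower in 0, 12 adjusted over the list alone (camera adjusted p = 0.00112; adjusted p = 0.141 with an estimated correlation). Higher ones included TYMS (1.36 ± 0.16), MCM2 (0.95 ± 0.11), MCM4 (0.66 ± 0.10) and CDT1 (0.61 ± 0.08). NF-kB and inflammatory response genes were lower in 6 of 12 cases and higher in 0, 7 and 1 adjusted over the list alone (camera adjusted p = 0.0031; adjusted p = 0.288 with an estimated correlation), such as CXCL8 (-2.14 ± 0.13) and CCL2 (-1.98 ± 0.20). Androgen and steroid metabolism genes were lower in 9 of 19 cases and higher in 2, 10 and 2 adjusted over the list alone (camera adjusted p = 0.00578; adjusted p = 0.141 with an estimated correlation), such as AKR1C3 (-1.82 ± 0.23, detected on 1 of 3 ETV1sh1 arrays) and HSD17B4 (-0.74 ± 0.10).

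The p53 targets were higher with ETV1sh1 in 8 of 20 cases and lower in 2, 10 and 2 adjusted over the list alone (camera adjusted p = 0.0031; adjusted p = 0.141 with an estimated correlation). TP53INP1 (1.56 ± 0.10), the death receptor TNFRSF10B (1.19 ± 0.09) and SESN1 (0.50 ± 0.09) were higher, while RRM2B (-1.37 ± 0.27), a ribonucleotide reductase subunit, was lower. Against shScr this list did not pass with ETV1sh1 (camera adjusted p = 0.122) or ETV1sh2 (0.458), and in the mean of both hairpins 4 of 20 rose and 5 fell (camera adjusted p = 0.995), with a median of 0.03, a mean of 0.05 and a direction of down, where fry called it in the direction of up (adjusted p = 0.0464). Unfolded protein response and ATF4 target genes were higher with ETV1sh1 in 10 of 26 cases and lower in 4, 11 and 6 adjusted over the list alone (camera adjusted p = 0.0294; adjusted p = 0.187 with an estimated correlation). The cystine transporter SLC7A11 (1.33 ± 0.11), the stress factor DDIT3 (1.14 ± 0.10) and the serine synthesis enzyme PSAT1 (1.05 ± 0.08) were higher, and the chaperone DNAJB9 (-1.74 ± 0.18) was lower. The steroid call (adjusted p = 0.459) and the unfolded protein response call (0.138) were lost among genes detected on all 9 arrays. The latter was lost also without ETV1sh1 2 (0.0581). Without ETV1sh1 3 or without ETV1sh2 1, 5 of the p53 targets were higher. Without any 1 of ETV1sh1 2, ETV1sh1 3 and the 3 ETV1sh2 arrays, 1 unfolded protein response gene was lower.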

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

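The test against a single graded response and the fits with background as a covariate or without both arrays of highest background were chosen only after the results they bear on were seen. Each value below is the log2 fold change of ETV1sh1 against ETV1sh2, positive where the gene was higher with ETV1sh1, and is listed because the direct limma test between the hairpins passed.

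Among genes of androgen response and prostate identity, the difference was 0.55 for HOXB13, 0.55 for TMPRSS2, -1.07 for FKBP5, -1.67 for PLPP1, 0.75 for CENPN and -1.04 for MAF. It was 0.84 for UGT2B17, 1.55 for UGT2B15 and 0.68 for CAMK2N1. Genes of the cell cycle and nucleotide supply had differences of 1.36 for TYMS, 0.66 for MCM4, 0.95 for MCM2, 0.61 for CDT1 and 0.35 for PRIM1. For mitotic genes and others of this class it was 0.36 for CDC20, 0.82 for ANLN, 0.53 for TTK, -0.84 for CCNB2, -0.35 for CDC25C, 2.20 for PRPS1 and -1.37 for RRM2B. Chemokines and inflammatory genes had differences of -2.93 for CXCL10, -2.84 for CCL8, -2.14 for CXCL8, -1.29 for CCL20, -1.98 for CCL2 and -0.57 for NFKBIA. Interferon-linked and antigen-presentation genes had differences of -1.33 for IFI44, -1.58 for SAMD9, -0.75 for IRF9, -1.43 for IFIT1, -1.65 for IFI27L2, -1.50 for HLA-DRA and -0.66 for CD74. CD74 did not pass with ETV1sh1 against shScr (adjusted p = 0.0553) but did without ETV1sh1 3 (0.0234), within a range of 0.0169 to 0.245 over the alternatives. Steroid and xenobiotic genes had differences of -2.69 for AKR1C2, -1.82 for AKR1C3, -2.39 for CYP11A1, -0.74 for HSD17B4 and -2.47 for CES1. For stress genes it was 1.56 for TP53INP1, 1.19 for TNFRSF10B, 0.50 for SESN1 and 1.05 for PSAT1. It was 1.33 for SLC7A11, 1.14 for DDIT3, -1.74 for DNAJB9 and 1.67 for HSPB8.

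Structural, neural and stromal genes had differences of 5.68 for STMN4, 2.87 for SYT11, 2.27 for KRT80 (2.265 before rounding), 1.36 for VIM and 2.99 for CAP2. It was 0.49 for COL1A1, -0.80 for S100A4, 0.58 for ENO2, 0.37 for NCAM1 and -1.49 for CBLN2. The remaining genes had differences of -0.97 for MMP7, -0.81 for RIPOR2, -0.81 for OPTN, 1.16 for GULP1, 0.82 for RPRML, -1.02 for DEFB132, 0.45 for AADAT and 0.91 for SLC4A4. It was -1.74 for PI3, -1.53 for FHL2, -2.07 for BRDT, 2.03 for HDDC2 and 2.62 for PPP1R14C. It was -3.08 for NPPC, -0.71 for SLC2A3 and -0.54 for SLC2A1. CES1 and DEFB132 were detected on 0 of the ETV1sh1 arrays, and against the detection floor CES1 was at least 3.49-fold and DEFB132 at least 1.87-fold lower with ETV1sh1 than with ETV1sh2. S100A4, likewise detected on 0 ETV1sh1 arrays, was at least 1.38-fold lower, and NCAM1, detected on 0 ETV1sh2 arrays, at least 1.15-fold higher. Near background, where fitted sizes are not exact, were AKR1C3, CXCL10 and PI3 (detected on 1 ETV1sh1 array each), NPPC, BRDT, CYP11A1, CCL2 and CD74 (on 2) and STMN4, PPP1R14C and SLC4A4 (on 2 ETV1sh2 arrays).

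Among gene lists, the median difference was -0.43 for androgen and steroid metabolism, 0.25 for DNA replication and S phase, 0.32 for p53 targets, -0.39 for interferon response, 0.20 for unfolded protein response and ATF4 targets and -0.36 for NF-kB and inflammatory response. With genes detected on no array of 1 group at their bound, the interferon median was -0.34, and the other 5 were unmoved. Each passed the camera threshold with the preset correlation, and 0 of the 6 did with an estimated correlation, where 5 had an unadjusted p under 0.05. A total of 2557 genes differed between the hairpins, against 0 in the other 9 of 10 splits of the 6 arrays, and 6 lists against at most 2, with too few splits for a share under 0.05.

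Outside the named genes, 217 of 3039 kept probes without a single gene name changed the same way with both hairpins. With ETV1sh1, 401 of these probes changed (206 higher, 195 lower), and with ETV1sh2, 582 (316 higher, 266 lower). They are listed because they lie outside the comparisons of named genes, and which genes they measure was not tested.

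A total of 114 genes were called in opposite directions by the hairpins, among them NPPC, CXCL10, CCL8 and CAP2. A single graded response, in which 1 hairpin acts more strongly than the other along the same genes, has no place for genes moved in opposite directions, and is argued against for those furthest past the threshold, since 29 of such genes were called at an adjusted p threshold of 0.01 and 27 with a 1.5-fold minimum, and CXCL10 was at -1.15 ± 0.11 with ETV1sh1 and 1.77 ± 0.11 with ETV1sh2. Array background and normalization are argued against for most of them, since 89 of the 114 or more stayed called in opposite directions with no background correction (109), median scaling (94), the authors' values (113) or the background covariate (89), though the count was 63 without shScr 2, 74 without shScr 3, 71 without ETV1sh1 1 and 53 without both arrays of highest background. Unintended targets of either hairpin, a different depth of ETV1 knockdown acting in a non-graded way, and differences between infections stay open and untested, because ETV1 was not detected and no transcript sequences were used here.

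Interferon response genes were called higher with ETV1sh2 in 15 of 26 cases and lower in 0, and with ETV1sh1 higher in 7 and lower in 2, where the list did not pass (camera adjusted p = 0.139) except without a filter on dim probes (0.0471), among genes detected on all 9 arrays (0.0304) and with fry (0.0130), over a range of 0.0130 to 0.420. Array background and normalization are argued against, since 14 of the 15 or more stayed called higher under each of the same 4 alternatives. A single deviating array is argued against as well, since 14 or 15 stayed called higher whichever of the 9 arrays was left out. All 3 groups were infected with a lentiviral hairpin construct, so a response to infection alone would be shared with shScr. A response to the RNA of this hairpin, differences between infections in lentivirus or cell culture, and an effect of lower ETV1 each could account for the rise. The design does not separate them.

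More genes were called higher than lower with both hairpins, at 59.0% and 61.1%. The lowest share under the same 4 alternatives was 58.0%, but all 4 keep the median of all genes above 0, so a common shift from normalization stays open; this was recognised after the share was seen. Dim probes are argued against as the whole cause, since the share among the brightest of 3 groups of equal size was 61.4% with ETV1sh1 and 58.4% with ETV1sh2, while among the dimmest it was 52.4% and 71.0%. A change in total RNA per cell stays open, since normalization to a common distribution removes it, and a biological difference between hairpins and control was not separable from infection.

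For the counts of changed genes against shScr, 2572 genes were called with ETV1sh1 against at most 1 in the other splits, and 3734 with ETV1sh2 against 0, and 9 lists against at most 4 and 6 lists against at most 5. Each of these comparisons has 10 splits of its 6 arrays, too few for a share under 0.05. For the mean of both hairpins, 1 of 100 drawn assignments of the 9 arrays out of 840 gave as many as 3489 genes, the real one, and the highest other gave 3385. That is a share under 0.05 for arrays assigned without regard to their group. For genes called the same way by both hairpins, 2 of 100 gave as many as 1445, with 1512 as the highest other, again a share under 0.05. The 3385 and the 1512 came from 1 assignment that only exchanged whole groups, and among 98 that mixed groups the highest were 1751 and 794. With a hairpin group in the place of shScr the counts were thus about as high, so they are not particular to hairpins against shScr. Mixed groups hold the differences between groups in their spread, which lowers their counts. Chance differences between infections are therefore not excluded. For the 7 lists of the mean contrast, 9 of 100 gave as many, with 9 lists as the highest other, so that chance could not be excluded for that number of lists.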

How the results depend on the processing

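Alternatives chosen only after seeing the data left out the 2 arrays least like their group, left out the 2 arrays of highest background, or used background as a covariate, and all others were planned. Signal over background set what was measurable, and ETV1 was detected on 0 of the 9 arrays. No slide block, no seed-match test and no ETV1 alternatives were run, and the mean of both hairpins has no fit of only the groups compared. Where no reason follows from the setting itself, the cause was not tested. A range of adjusted p is over all alternatives, which for lists include fry and the estimated correlation beside camera.

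Over all planned and added alternatives, 173 of 182 results for named genes were called, and of 3888 recomputed values 3865 kept their call and direction, 23 lost the call and 0 reversed. The 9 uncalled ones passed in 15 of 205 alternatives, most of these for KLK2, which passed with ETV1sh1 and with ETV1sh2 without shScr 1 (adjusted p = 0.00816, range 0.00631 to 0.202, and 0.0117, range 0.00725 to 0.572). Of the 28 called list results, 633 of 693 recomputed values kept the call and 60 lost it, with 0 reversed. Uncalled lists passed in 41 of 1881 alternatives, and their direction differed from the original camera direction in 103. Both counts take in fry, which does not compare a list with other genes and called more lists than camera in every contrast. Of the 1445 genes called the same way by both hairpins, 621 with a 1.5-fold minimum and 629 at an adjusted p threshold of 0.01 were kept by construction. Shared genes were not counted for fits of only the groups compared or for probes counted as probes. In the other settings 980 (without the 2 arrays of highest background) to 1419 were called again, 1008 to 1142 without each of the 9 arrays in turn, and 1186 of 1187 among genes detected on all 9 arrays.

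With a 1.5-fold minimum, which by construction calls fewer genes, 1360 genes were called with ETV1sh1, 2050 with ETV1sh2, 1426 for the mean and 1419 between hairpins, and 621 the same way by both. At an adjusted p threshold of 0.01 these were 1194, 2163, 1906, 1378 and 629. Fitting only the groups compared gave 1687 genes with ETV1sh1, of them 982 higher, 3476 with ETV1sh2, 2986 between hairpins and 988 the same way by both. The median SD of a gene was 0.18 with shScr, 0.14 with ETV1sh1 and 0.11 with ETV1sh2. Leaving out the tight ETV1sh2 arrays goes with the lower ETV1sh1 count, and leaving out the wide shScr arrays with the higher count between hairpins. Fewer arrays per fit act on all comparisons, and these causes were not separated. The number of lists called for ETV1sh1, ETV1sh2, the mean and the difference was 3, 2, 3 and 0 with an estimated correlation, and 17, 13, 16 and 14 with fry. For p53 targets in the mean contrast, fry called the list higher (median 0.032, adjusted p = 0.0464, range over the alternatives 0.0464 to 0.999), opposite in direction to camera, which did not call it and compares the list with other genes.

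The correlation between hairpins was 0.590 among genes detected on all 9 arrays, 0.592 without the 2 arrays of highest background and 0.596 with the background covariate. With split controls it was 0.363, 0.389, 0.404, 0.416, 0.438 and 0.320. No control array is shared there, and each side rests on 1 or 2 control arrays. Leaving out each array in turn gave 0.505 (without ETV1sh1 3) to 0.592 (without shScr 3).

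Leaving out each array in turn gave 1778 to 2340 genes with ETV1sh1, 2797 to 3801 with ETV1sh2, 2871 to 3432 for the mean, 1758 to 3234 between hairpins and 1033 to 1339 the same way by both. The lists called numbered 7 to 9, 6 to 6, 5 to 7 and 5 to 6. Without the 2 arrays least like their group the counts were 2312, 3928, 3297, 2949 and 1327, without the 2 of highest background 1921, 3551, 3047, 2064 and 1150, and with the background covariate 3043, 3681, 3801, 2473 and 1645. Without ETV1sh1 3, 1007 genes were higher with ETV1sh1. The share of higher genes against shScr ran from 54.6% to 63.9% over all alternatives fitted to the 3 groups at the same threshold.

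The replicate number as a block gave 2365, 3588, 3312 and 2344 genes and 1362 the same way by both, with a correlation of 0.545. The numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.269 to 0.265 across genes, 2 of 9 pairs were over 0.1, and 5 of 9 arrays were closest to their own number. The block ended the calls of the leukocyte markers with ETV1sh1 (adjusted p = 0.0555, range 0.000577 to 0.442) and of the unfolded protein response list between hairpins (0.0568, range 0.000188 to 0.187), and changed no other call of a list or named gene.

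Single arrays decided several calls near the threshold. For the mean of both hairpins, androgen-repressed genes lost the call without shScr 1 (0.0780), shScr 3 (0.0558), ETV1sh1 1 (0.0512), ETV1sh1 2 (0.0541), ETV1sh1 3 (0.0717), ETV1sh2 1 (0.0571) or ETV1sh2 3 (0.0562), within 0.000319 (fry) to 0.182. Hypoxia genes lost it without shScr 1 (0.0726), shScr 3 (0.107), ETV1sh1 1 (0.0512), ETV1sh1 2 (0.0568) or ETV1sh2 3 (0.0562), within 0.00784 to 0.323. The NF-kB list gained it without shScr 1 (0.0351) or ETV1sh2 1 (0.0493), within 0.0183 to 0.419. With ETV1sh1, leukocyte markers lost it without shScr 1 (0.0807), shScr 3 (0.0513) or ETV1sh1 1 (0.0687), and neuroendocrine markers without shScr 1 (0.0611) or ETV1sh1 1 (0.0687), within 0.000295 (fry) to 0.163. Between hairpins, the unfolded protein response list lost it without ETV1sh1 2 (0.0581). Among named genes with ETV1sh1, SYP lost it without shScr 1 (0.0572) or shScr 3 (0.0503), within 0.00534 to 0.102, and GULP1 without ETV1sh1 1 (0.0685), ETV1sh1 2 (0.0511) or ETV1sh1 3 (0.0847), within 0.00845 to 0.0847. TAGLN lost it without ETV1sh1 1 (0.0725) or ETV1sh1 2 (0.0638), within 0.00592 to 0.145, and HLA-DRA without ETV1sh1 1 (0.0521), within 0.00446 to 0.0662. With ETV1sh2, RRM2 lost it without ETV1sh2 2 (0.0610) or ETV1sh2 3 (0.0576), within 0.00226 to 0.0610.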

Other observations

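The 3 lists tested in this part were chosen after the data were seen, each prompted by genes that stood out, and those genes were left out of the tests.

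Beyond the genes already named, 5 of the genes called in opposite directions by the hairpins are given here, chosen after their values were seen and not as a class. The kinase SGK1 fell by 0.87 with ETV1sh1 and rose by 1.39 with ETV1sh2, the transcription factor CEBPD fell by 0.80 and rose by 1.01, and the imprinted gene NDN fell by 1.17 and rose by 0.92. The cytokine receptor TNFRSF12A rose by 1.57 and fell by 0.62, and the angiogenic factor ANGPT2 rose by 0.99 and fell by 0.72 (detected on 1 ETV1sh2 array).

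A candidate explanation for CES1 and other liver-type genes among the highest with ETV1sh2 is that hepatocyte genes rose as a class. Of 15 tested genes from a list of 47, 4 rose with ETV1sh2 and 1 fell, with a camera p of 0.0434 in the direction of up, which met the prediction written before the test. Adjusted over the 3 lists of this part the p was 0.130, and with an estimated correlation it was 0.0745. Requiring the adjusted p was decided after the unadjusted p had been seen, and the question is left open on that stricter ground. Of the members, which are named after their values were seen, the alcohol dehydrogenase ADH1C (1.84 ± 0.13), GSTA2 (1.59 ± 0.20), CYP2E1 (1.41 ± 0.12) and CPS1 (0.71 ± 0.14) rose, the clotting factor F5 (-0.82 ± 0.10) fell, and albumin (ALB, 0.27 ± 0.17, adjusted p = 0.252) did not pass. GSTA2 was detected on 2 of 3 shScr arrays, near background.

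The rise of AKR1C genes with ETV1sh2 could come from the oxidative stress regulator NRF2. Of 20 other NRF2 targets tested from a list of 26, 3 rose and 6 fell, with a camera p of 0.0912 in the direction of down (adjusted 0.137). The prediction written before the test took either a p of 0.05 or more or a direction of down as evidence against a rise, and both came out so. A p above the threshold does not exclude a rise, and the direction of down did not pass the threshold itself (0.375 with an estimated correlation), so the class was not shown to rise and a rise is not excluded.

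Microtubule genes may have risen as a class with both hairpins, as TUBB3, MAPRE3 and DYNLRB1 were among the highest with both and STMN4 with ETV1sh1. Of 42 others tested from a list of 46, 15 rose and 5 fell in the mean of both hairpins, with a camera p of 0.209 in the direction of up. The class was not set apart from other genes by this test, and for the same reason it is not excluded. Among members named after their values were seen, MAP2 (1.20 ± 0.19), MAP1LC3A (0.86 ± 0.09) and MAP1A (0.74 ± 0.16) rose, and DYNLL2 (-0.61 ± 0.10) and MAPRE2 (-0.53 ± 0.12) fell. MAP2 and MAP1A were detected on 2 of 3 shScr arrays, near background.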
